A study of Danio rerio with 12 samples.

How the data were processed

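Whole zebrafish larvae were exposed to waterborne PFOS from 2 to 5 days post fertilization at 0.03, 0.3 or 1 ppm, or to 0.2% DMSO alone, and 10 larvae were pooled for each of 12 stranded poly-A RNA-seq libraries, 3 per group. The submitters' notes name CASAVA, STAR 2.5.1b, RSEM 1.2.28, DESeq2 1.10.1 and the genome build GRCz10, without the settings of each step. The deposited files hold one value per gene, which the authors call normalized counts, rounded to whole numbers. Because they are neither raw counts nor scaled to a fixed total, the deposited unit is recorded as a score, and each value is a read count divided by a factor of its library. The factors were estimated from the spacing of the values and lay between 0.802 and 1.30. The files total 24061372 to 31907243 normalised counts per library, which corresponds to an estimated 21610000 to 34890000 reads. The deposited table of the whole series repeats the per-sample values and was not used. No genome of that build was at hand, so no coordinates are given. Intervals and limits of detection that need raw counts are not given.

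Groups, comparisons, gene lists, naming rule and most alternatives were set before the data were examined. A quasi-likelihood fit of raw counts had been planned and was not used, because the values are already normalised. Instead limma 3.58.1 in R 4.3.3 was fitted to log2 of the deposited value plus 1 with no further scaling, over all 12 libraries with 1 coefficient per group and a mean-variance trend in the empirical Bayes step. Genes with a value of at least 10 in at least 3 libraries were kept, 22320 of 26873. Each dose was compared with the control, neighbouring doses with each other, all 3 doses jointly, and a slope was fitted on the order of the 4 groups. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p of a single gene comes from limma. Group values are means with SD of 3 libraries, and the smallest p an exact test of 3 against 3 libraries allows is 0.1.

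Genes are named by a rule. In each dose comparison and the trend these are up to 10 genes that rose and 10 that fell with the largest change, among called genes with a mean of at least 1 CPM, a symbol that is not a clone or locus name and, for doses, no overlap between the groups. Added to them are up to 4 members of each list with the smallest p at 1 ppm, the 5 genes of smallest p where a comparison called fewer than 10, and a panel of 22 genes of interest for PFOS, of which 19 were tested. The lists, 43 of pathways, tissues, cell types and signs of handling, held 1180 members, of which 1126 matched a name in the files and 1071 were tested. Lists with at least 5 tested members, 42 of them, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists of a comparison. Members were also adjusted over the list alone. The vitellogenin list had too few members tested.

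Replicate numbers may mark a shared batch, so deviations from group means were correlated between libraries. Every same-number pair was above 0.1 for 0.3 ppm and the control (0.145 to 0.286), for 1 ppm and the control (0.119 to 0.478), for 1 and 0.3 ppm (0.280 to 0.460) and for 0.3 and 0.03 ppm (0.116 to 0.338). For 0.03 ppm and the control the lowest pair was 0.0776. The highest pair of different numbers was -0.0106, 0.204, -0.0753 and 0.0892 in the first 4 comparisons and 0.226 in the last. For 1 ppm and the control it thus exceeded the lowest same-number pair, so the numbers mark a batch only loosely there. Because their same-number pairs were all above 0.1, the first 4 comparisons are also given with a term for the replicate number.

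The method was tested on simulated data with the observed spread. At 1 ppm it recovered 4% of genes changed 1.5-fold, 44% of those changed 2-fold, 90% of those changed 4-fold and 98% of those changed 8-fold, with 50 genes at each size and 6 false calls among 22089 unchanged genes. With no changed genes it made 0 calls at each of the other doses. A list shifted as a whole was called, and 0 of the other lists were. Genes were drawn independently there, whereas members of real lists vary together, with an estimated correlation of 0.519 for the liver markers. The simulation therefore does not show how often such lists are called falsely. Its changed genes, 50 at each size, also outnumber the 31 called at 1 ppm in the real data. More changed genes loosen the adjusted threshold, so the shares recovered may be too high for these data. Alternatives covered the scaling, the low-value filter, the pseudocount, the weights of the libraries, the empirical Bayes step, the replicate term, the coding of dose, the list test and the omission of each library or replicate. Principal components were computed in R, and figures were drawn with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.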

Results

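The series measured messenger RNA in whole wild-type zebrafish larvae exposed through the water to perfluorooctanesulfonate (PFOS), a persistent surfactant, from 2 to 5 days post fertilization. There were 4 groups of 3 libraries, each library made from 10 pooled larvae: a solvent control (0.2% DMSO) and PFOS at 0.03, 0.3 and 1 ppm. The deposited values are normalised read counts per gene, rounded to whole numbers, and their total per library was between 24061372 and 31907243. The number of reads behind them, estimated from the steps between the values, ran from 21610000 to 28170000 per library in the control, 25010000 to 30110000 at 0.03 ppm, 24230000 to 31090000 at 0.3 ppm and 28300000 to 34890000 at 1 ppm. The files named 26873 genes, of which 22320 were tested. The labels do not say whether replicates came from separate clutches or tanks, so each p measures the spread between these libraries.

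The epidermis list took 8.60% to 11.6% of all normalised counts in the 4 libraries of replicate 2 and 5.09% to 8.01% in the other 8. The first principal component carried 28% of the variance and placed the replicate 2 libraries between 31.8 and 49.99, and the second carried 15.9% and set control replicate 1 apart at -61.9. Liver transcripts took 1.15%, 1.26% and 0.878% of the counts in control replicates 1, 2 and 3, and 1.39%, 1.41% and 1.35% in those of 1 ppm. No pair of libraries held identical values.

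**Figure D1:**
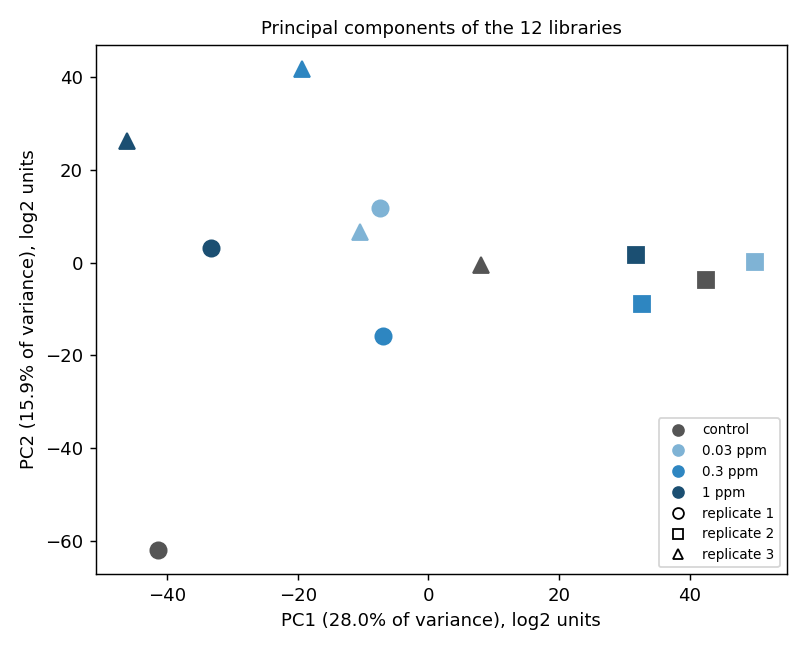
Positions of the 12 libraries on the first and second principal components of log2 normalised counts, coloured by dose group and marked by replicate number. The replicate 2 libraries lie between 31.8 and 49.99 on the first component, and control replicate 1 lies at -61.9 on the second.

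The lowest dose was compared with the control to ask whether 0.03 ppm PFOS already changed gene expression. trim63a (ENSDARG00000028027), a ubiquitin ligase of muscle, fell from 1713 ± 264 to 849 ± 126 normalised counts (SD, n = 3), a log2 fold change of -1.01 (limma adjusted p = 0.0344). mkrn1 (ENSDARG00000041665), another ubiquitin ligase, fell from 1496 ± 200 to 767 ± 49.7, and DUSP27 (ENSDARG00000099889), an atypical phosphatase of muscle, from 1383 ± 249 to 556 ± 82.9. calcoco1b (ENSDARG00000016391), of a family of autophagy receptors, fell 4.05-fold, from 292 ± 53.5 to 73.0 ± 22.6 (adjusted p = 0.0278). lygl1 (ENSDARG00000056874), which encodes a goose-type lysozyme, fell from 533 ± 38.8 to 205 ± 36.0 (adjusted p = 0.0223).

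These 5 were the genes that the naming rule took among 13 called at 0.03 ppm, all of them lower. The others carry clone names. The clone-named gene zgc:153932, chosen after its values were seen, fell from 4709 ± 1258 to 755 normalised counts, with a log2 fold change of -2.61 (adjusted p = 0.00485). At an unadjusted p under 0.05 there were 780 genes, where chance alone gives 1116. The groups did not overlap for 7.40% of genes, against 10% by chance. Leaving out 1 library gave 2 genes without control replicate 1, 2 without control replicate 3, 0 without 0.03 ppm replicate 1, 8 without its replicate 2 and 2 without its replicate 3. With only these 2 groups in the fit 3 genes were called, and rescaling to equal totals gave 6.

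Of the 42 gene lists tested, 7 fell and 2 rose at 0.03 ppm with the preset correlation of camera, and 0 of these calls held with an estimated correlation or with fry's test for change in one direction, where the smallest adjusted p were 0.719 and 0.571. Interferon response genes had the largest median change: 19 of 20 members were lower, with a median log2 fold change of -0.57 (adjusted p = 1.11e-09, or adjusted p = 0.719 with an estimated correlation). Adjusted over the list alone, 4 interferon genes were called lower, against 0 over all genes tested. stat1b (ENSDARG00000076182), a transcription factor of interferon signalling, was at 128 ± 36.6 normalised counts in the control and 19.7 ± 11.6 at 0.03 ppm (adjusted p = 0.0519). All 35 tested cytosolic ribosome genes were lower, with a median of -0.26 (adjusted p = 2.05e-06, or adjusted p = 0.991 with an estimated correlation). In the skeletal muscle list 32 of 35 were lower, with a median of -0.25 (adjusted p = 2.62e-06, or adjusted p = 0.991 with an estimated correlation). ckma, the muscle creatine kinase, had 164112 ± 9275 normalised counts in the control and 106131 ± 23388 at 0.03 ppm, and did not pass the test on its own (adjusted p = 0.998).

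Neuron and synapse genes were lower in 35 of 39 members (median -0.31, adjusted p = 0.00123), lens crystallins in 18 of 20 (median -0.41, adjusted p = 0.0129) and neutrophil and macrophage markers in 26 of 32 (median -0.20, adjusted p = 0.000637). Cartilage, bone and collagen genes were higher in 27 of 31 (median 0.22, adjusted p = 5.88e-06) and liver markers in 26 of 31 (median 0.23, adjusted p = 0.0129). Nuclear respiratory chain genes were lower in 30 of 34 (median -0.09, adjusted p = 0.0338). With an estimated correlation the adjusted p was 0.903 for the cartilage list and 0.991 for the other 5. Leaving out single controls or whole replicates ended the calls of all of these lists except interferon. Without replicate 1 the cartilage list had adjusted p = 0.443 and the neuron list 0.934 with its direction turned, and without replicate 2 the muscle list had 0.143, the lens list 0.466, the leukocyte list 0.736 and the respiratory chain list 0.736. Without control replicate 1 the adjusted p was 0.205 for the lens list and 0.210, turned, for the neuron list. Without control replicate 2 it was 0.0740 for the ribosome list, 0.421 for the lens list, 0.535 for the leukocyte list and 0.594 for the respiratory chain list. Without replicate 3 the liver list had 0.979 and the respiratory chain list 0.599, both turned. Without control replicate 3 they had 0.704, turned, and 0.186.

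At 0.3 ppm trim63a was at 706 ± 67.6 normalised counts, 2.41-fold below the control (adjusted p = 0.00599), and fbxo32 (ENSDARG00000040277), which encodes atrogin-1, the ubiquitin ligase of muscle atrophy, fell from 740 ± 303 to 154 ± 7.37 (log2 fold change -2.18, adjusted p = 0.0408). stat1b fell from 128 ± 36.6 to 16.0 ± 7.0 (log2 fold change -2.97, adjusted p = 0.0239). krt96 (ENSDARG00000095147), a keratin, fell from 1581 ± 257 to 276 ± 98.0 (log2 fold change -2.56, adjusted p = 0.00522). noxo1a (ENSDARG00000041294), an organizer of NADPH oxidase, fell from 357 ± 69.8 to 122 ± 27.4 (adjusted p = 0.0420).

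The other named genes at 0.3 ppm were ppp1r27b, a regulatory subunit of a protein phosphatase, at 255 ± 93.6 normalised counts in the control and 59.0 ± 13.9 (adjusted p = 0.0248), and plekhs1 at 882 ± 456 and 186 ± 54.6 (adjusted p = 0.0328). calcoco1b had a log2 fold change of -2.05 and DUSP27 one of -1.38. In a gene also named PLEKHS1 (ENSDARG00000070041) the mean was 244 ± 72.4 in the control and 67.7 ± 18.2 (adjusted p = 0.0280). In all, 29 genes were called, 28 lower and 1 higher. The higher one, FO904928.1 (ENSDARG00000100529), chosen after its values were seen, was listed at 0 in the 6 libraries of the control and 0.03 ppm and between 16 and 72 in the 6 of 0.3 and 1 ppm. There were 630 genes at an unadjusted p under 0.05, and the groups did not overlap for 7.09% of genes, against 10% by chance. With a term for the replicate number 43 genes were called, 42 of them lower, and all 29 were among them. Without 1 library the count was 14, 15 or 10 for control replicates 1, 2 and 3 and 6, 12 or 16 for those of 0.3 ppm, and it was 10 with only the 2 groups in the fit and 18 after rescaling to equal totals.

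At the level of lists, 2 fell and 5 rose at 0.3 ppm, and 0 held with an estimated correlation or with fry's test for change in one direction, where the smallest adjusted p were 0.232 and 0.426. Interferon genes were lower in 17 of 20 members, with a median of -0.46 (adjusted p = 1.11e-11, or adjusted p = 0.232 with an estimated correlation). Over all genes tested 1 of them, stat1b, was called, and 5 were when adjusted over the list alone, irf1a and mxc among them. fry's test for change in either direction gave adjusted p = 0.0261 for this list. Cartilage, bone and collagen genes were higher in 30 of 31 members (median 0.35, adjusted p = 2.01e-09, or adjusted p = 0.232 with an estimated correlation). The matrix proteoglycan gene dcn, for example, had 2299 ± 313 normalised counts in the control and 3143 ± 79.7 at 0.3 ppm (adjusted p = 0.736 on its own). Erythrocyte genes were higher in 18 of 18 members (median 0.37, adjusted p = 1.07e-07, or adjusted p = 0.319 with an estimated correlation) and heat shock genes in 17 of 22 (median 0.36, adjusted p = 1.93e-05, or adjusted p = 0.232 with an estimated correlation).

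All 13 transcripts of the mitochondrial genome were higher at 0.3 ppm (median 0.22, adjusted p = 0.00345), as were 14 of 16 heart muscle genes (median 0.30, adjusted p = 0.0245), while 24 of 32 neutrophil and macrophage markers were lower (median -0.14, adjusted p = 0.0234). Each of these 3 lists had adjusted p = 0.997 with an estimated correlation. The call of the mitochondrial list ended without control replicate 2 (0.0834), control replicate 3 (0.0733) or replicate 3 (0.1001), and that of the heart list without replicate 1 (0.140), control replicate 1 (0.125) or control replicate 2 (0.118). The leukocyte list had 0.0738 without replicate 3 and turned direction without replicate 2 (0.720) and without control replicate 2 (0.960).

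At 1 ppm, the highest dose, fbxo32 fell 4.86-fold, from 740 ± 303 to 144 ± 20.7 normalised counts (log2 fold change -2.28, SE 0.361, n = 3, limma adjusted p = 0.0293), and trim63a fell 2.34-fold, from 1713 ± 264 to 725 ± 31 (log2 fold change -1.23, SE 0.150, adjusted p = 0.009996). krt96 fell from 1581 ± 257 to 260 ± 59.6 (SE of the log2 change 0.293, adjusted p = 0.00512). mpeg1.2 (ENSDARG00000043093), a perforin-like gene of macrophages, fell from 1280 ± 424 to 363 ± 86.2 (log2 fold change -1.79, adjusted p = 0.0388), and the chemokine gene ccl20a.3 (ENSDARG00000101040) from 79.0 ± 30.8 to 16.3 ± 9.45 (adjusted p = 0.0488). Higher than in the control was sb:cb1058 (ENSDARG00000099819), at 546 ± 50.2 and 917 ± 80.2 (log2 fold change 0.75, SE 0.124, adjusted p = 0.0388).

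calcoco1b stood at 65.3 ± 8.74 normalised counts, 4.38-fold below the control (adjusted p = 0.0111), ppp1r27b at 47.0 ± 10.8 (log2 fold change -2.37), lygl1 at 209 ± 21.5, mkrn1 at 790 ± 62.9 and DUSP27 at 573 ± 78.0. gna15.2, which encodes a G protein alpha subunit, fell from 156 to 54.0 (log2 fold change -1.51, adjusted p = 0.0465), plekhs1 from 882 to 180 (adjusted p = 0.0279), and URGCP (ENSDARG00000036767) from 1379 to 219 (log2 fold change -2.69, adjusted p = 0.0212). The clone-named zgc:153932 and si:dkey-239b22.1, both chosen after their values were seen, had the smallest adjusted p among the genes that fell, 0.000852 for each. zgc:153932 was at 4709 ± 1258 in the control and 567 ± 221 at 1 ppm, and si:dkey-239b22.1 at 6878 and 1097.

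The 31 calls at 1 ppm were 29 lower and 2 higher, with 1058 genes at an unadjusted p under 0.05 and no overlap between the groups for 8.75% of genes, against 10% by chance. With a term for the replicate number 58 genes were called, 53 lower and 5 higher, and all 31 were among them. The 27 added genes were 24 lower and 3 higher. They included stat1b (limma adjusted p = 0.0301 with that term, 0.104 without), irg1l (0.00735 and 0.0645) and the granulin gene grn2 (0.0301 and 0.235). pdk2b, a kinase that inhibits pyruvate dehydrogenase, was also among them (0.0428 and 0.153), at 4625 ± 168 normalised counts in the control and 2346 ± 391 at 1 ppm. Further added genes, chosen after their values were seen, were the interferon-inducible NMI (828 ± 88.8 and 394 ± 154), PARP14 (337 and 178) and the proteasome activator psme4a (594 and 272), all lower. Leaving out 1 library gave 11 genes without control replicate 3, 4 without 1 ppm replicate 1, 47 without its replicate 2 and 5 without its replicate 3. With only the 2 groups in the fit 3 genes were called, and with a weight estimated for each library, a setting chosen after the data were seen, 768 were, 335 higher and 433 lower.

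**Figure D2:**
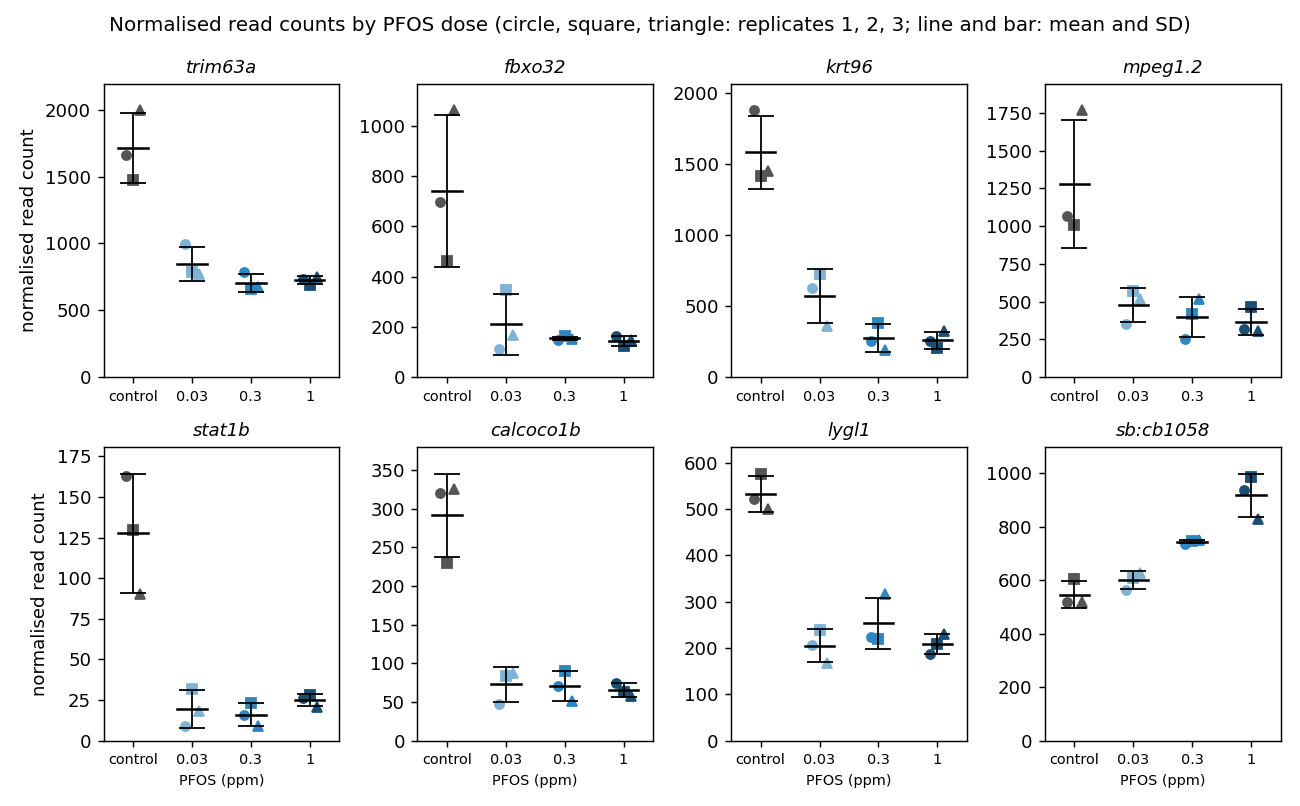
Normalised read counts of 8 genes by PFOS dose in ppm, with 1 marker per library, its shape giving the replicate number, and lines and bars for the group mean and SD (n = 3). trim63a stands at 1713 in the control and at 849, 706 and 725 at the 3 doses, while sb:cb1058 goes from 546 to 917.

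Liver markers were higher at 1 ppm in 29 of 31 members, with a median log2 fold change of 0.61 (camera adjusted p = 2.06e-14, or adjusted p = 0.367 with an estimated correlation). Their mean log2 value was 11.09, 11.23 and 10.47 in control replicates 1, 2 and 3. At 1 ppm it was 11.47, 11.38 and 11.63, so the low control replicate 3 added to the rise of these markers. Adjusted over the list alone 4 were called higher, against 0 over all genes tested: the transferrin gene tfa (13154 ± 3810 normalised counts in the control, 26578 ± 4810 at 1 ppm), the apolipoprotein gene apobb.1 (17642 ± 3748 and 35745 ± 3531), ces3 (963 and 1819) and vtnb (707 and 1161). Lipoprotein transport genes were higher in 20 of 27 (median 0.27, adjusted p = 3.18e-05, or adjusted p = 0.370 with an estimated correlation), with 4 called higher adjusted over the list alone. Among these, apoea had 8098 ± 1541 and 15742 ± 2093 and apoa4b.3 had 1349 ± 108 and 2242 ± 313. All 18 bile acid synthesis and transport genes were higher (median 0.43, adjusted p = 1.12e-07, or adjusted p = 0.276 with an estimated correlation), such as abcb11b, the bile salt export pump, at 249 ± 120 and 464 ± 57.4. Intestine markers were higher in 22 of 26 (median 0.42, adjusted p = 3.74e-07) and xenobiotic metabolism genes in 28 of 35 (median 0.28, adjusted p = 1.79e-06), each with adjusted p = 0.370 with an estimated correlation. cyp2k18 of the latter had 487 ± 64.6 and 904 ± 193, and vil1 of the former, the villin of the brush border, 1939 ± 420 and 3416 ± 598.

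Acute phase and complement genes were higher at 1 ppm in 23 of 31 (median 0.54, adjusted p = 1.23e-05, or adjusted p = 0.414 with an estimated correlation). cfh, complement factor H, had 703 ± 113 normalised counts in the control and 1416 ± 292 at 1 ppm. The single member called adjusted over the list alone was irg1l, which was lower, at 825 ± 482 and 174 ± 81.1. Fatty acid oxidation genes were higher in 28 of 31 (median 0.14, adjusted p = 0.000577, or adjusted p = 0.507 with an estimated correlation). Erythrocyte genes were higher in 17 of 18 (median 0.44, adjusted p = 1.96e-07, or adjusted p = 0.363 with an estimated correlation), klf1, the erythroid transcription factor, at 42.7 ± 5.13 and 78.7 ± 9.24. Cartilage, bone and collagen genes were higher in 29 of 31 (median 0.34, adjusted p = 2.35e-08, or adjusted p = 0.276 with an estimated correlation), and dcn, at 3261 ± 187, was called adjusted over the list alone. Mitochondrial genome transcripts were higher in 12 of 13 (median 0.38, adjusted p = 3.74e-06, or adjusted p = 0.416 with an estimated correlation).

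Interferon response genes were lower at 1 ppm in 18 of 20 members (median -0.54, adjusted p = 3.79e-10, or adjusted p = 0.276 with an estimated correlation). Adjusted over the list alone 7 were called lower, among them stat1b (128 ± 36.6 normalised counts in the control and 25 ± 3.61 at 1 ppm), irf1a (98.7 ± 29.0 and 38.7 ± 22.1), mxc (190 ± 38.1 and 76.0 ± 19.5) and isg15 (44.0 ± 19.0 and 14.7 ± 2.08). fry's test for change in either direction gave adjusted p = 0.0262 for this list. Neutrophil and macrophage markers were lower in 29 of 32 (median -0.26, adjusted p = 1.48e-05, or adjusted p = 0.370 with an estimated correlation), with grn2 (311 ± 212 and 74.0 ± 48.6) the member called adjusted over the list alone. The leukocyte call ended without replicate 2 (adjusted p = 0.144) and without control replicate 2 (0.107). mpx, the peroxidase of neutrophils, had 216 ± 49.6 and 193 ± 14.4 and was not called.

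Lists called with larger adjusted p at 1 ppm were heart muscle (14 of 16 higher, median 0.30, adjusted p = 0.00303) and glia and myelin (19 of 20 higher, median 0.21, adjusted p = 0.00468). Nuclear respiratory chain genes (26 of 34 higher, median 0.07, adjusted p = 0.0115) and steroid and glucocorticoid response genes (14 of 21 higher, median 0.30, adjusted p = 0.0169) were also called. The p53 and cell death list was lower in 14 of 23 members (median -0.145, adjusted p = 0.0483). With an estimated correlation the adjusted p were 0.446, 0.741, 0.846, 0.276 and 0.446 in that order. The heart call ended without control replicate 1 (0.0638), the glia call without control replicate 2 (0.139) or replicate 3 (0.527), and the respiratory chain call without control replicate 1 (0.580) or replicate 3 (0.386). The steroid call ended without replicate 1 (0.0585) or control replicate 3 (0.0653), and the p53 call without replicate 2 (0.209), replicate 3 (0.211), control replicate 2 (0.522) or control replicate 3 (0.0616). In total 14 lists rose and 3 fell, and 0 held with an estimated correlation or with fry's test for change in one direction, where the smallest adjusted p were 0.276 and 0.206.

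PPAR targets and receptors, a list chosen because PFOS is known to activate PPAR alpha in rodents, did not pass the test at 1 ppm: 17 of 24 were higher, with a median of 0.10 (camera adjusted p = 0.219). Its receptor gene pparaa had 192 ± 11.9 normalised counts in the control and 223 ± 58.4 at 1 ppm, and cpt1b of fatty acid import into mitochondria 819 ± 211 and 899 ± 60.8. The 1 member called adjusted over the list alone was pdk2b, which was lower. Heat shock (adjusted p = 0.0513), ER stress (0.0545), sterol synthesis (0.0866), fatty acid and triglyceride synthesis (0.143), NRF2 oxidative stress (0.331), cell cycle (0.671) and thyroid axis genes (0.750) did not pass either. hmox1a, a marker of oxidative stress, had 277 ± 53.1 and 322 ± 159, and cyp7a1, the rate-limiting enzyme of bile acid synthesis, 412 ± 24.5 and 604 ± 203. None of the 19 panel genes tested was called over all genes at any dose.

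**Figure D3:**
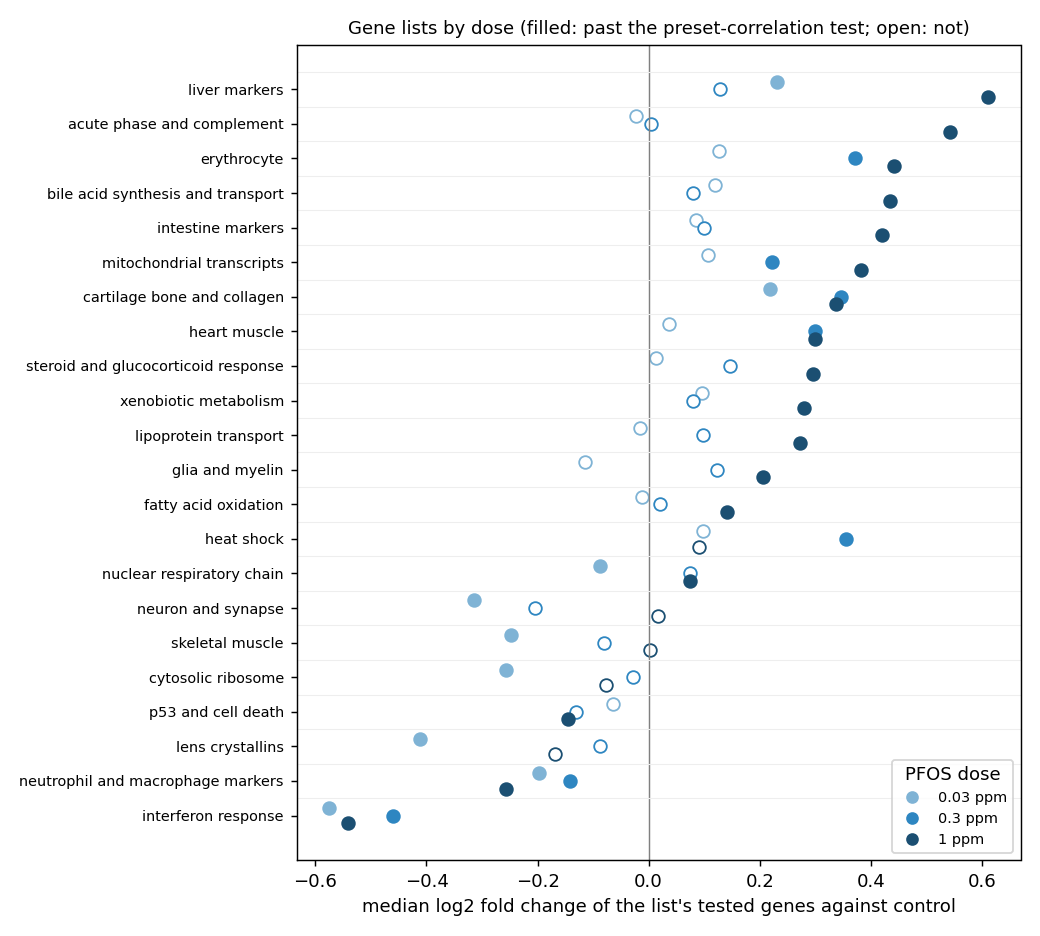
Median log2 fold change against the control of the 22 gene lists called at 1 or more doses, with 1 point per dose, filled where the list was called by camera with its preset correlation. The interferon list lies at -0.57, -0.46 and -0.54 from the lowest to the highest dose, and the liver list at 0.23, 0.13 and 0.61.

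The doses were then compared with each other to ask whether the changes grew with exposure. Of 36 genes called at any of the 3 doses, 13 were called at all of them and all 13 were lower, trim63a, mkrn1, DUSP27, calcoco1b and lygl1 among them. The rest of the 13 carry clone names. si:ch211-226h7.6 and si:ch211-226h7.8 share the name of a clone and may not be independent calls. Another 11 were called at both 0.3 and 1 ppm, krt96, fbxo32, ppp1r27b and plekhs1 among them. The 13 had a median absolute log2 fold change of 1.94, 2.07 and 2.07 at 0.03, 0.3 and 1 ppm, and being called at every dose selects genes with a large change at the lowest. For all 36 it was 1.59, 2.09 and 2.24, with the largest change at 1 ppm in 22. Of the 36, 13 were called at 0.03 ppm, 29 at 0.3 ppm and 31 at 1 ppm. The selection therefore favours larger changes at the higher doses. A joint test of the 3 doses called 21 genes, of which 20 were lower at every dose and 1, FO904928.1, was of mixed direction. For these 21 the median was 1.603, 2.11 and 2.37, and the change was largest at 0.03 ppm in 3, at 0.3 ppm in 7 and at 1 ppm in 11. The joint count was 4, 13 and 3 without control replicates 1, 2 and 3, 10 without 0.03 ppm replicate 1, 7 without 0.3 ppm replicate 1, 12 without 1 ppm replicate 1, 7 without its replicate 3, and 8 after rescaling to equal totals. With all 4 libraries of replicate 1, or of replicate 3, left out, limma called 0 genes at each dose and in the joint test, and without those of replicate 2 it called 7, 18 and 26 at the doses and 11 jointly.

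Across the ordered doses, krt96 fell by 0.89 on the log2 scale per step (adjusted p = 0.0399) and sb:cb1058 rose by 0.26 (SE 0.0368, adjusted p = 0.0424). sb:cb1058 stood at 546, 600, 744 and 917 normalised counts from the control to 1 ppm, and krt96 at 1581, 571, 276 and 260. FO904928.1 was the only other gene called for the trend (adjusted p = 0.0399), and 1241 genes had an unadjusted p under 0.05. With a term for the replicate number 9 genes were called for the trend, 2 higher and 7 lower. The trend called 0 genes with a slope on the dose in ppm or without any one of the 3 controls, 0.03 ppm replicate 1, 0.3 ppm replicate 2 or 1 ppm replicate 1. It called 6 without 0.03 ppm replicate 2, 1 without its replicate 3, 30 without 1 ppm replicate 2 and 1 without its replicate 3. Of the lists, 15 rose and 4 fell along the doses, and 0 held with an estimated correlation or with fry's test for change in one direction, where the smallest adjusted p were 0.297 and 0.113. Liver markers rose by a median of 0.16 per step (adjusted p = 3.79e-11, or adjusted p = 0.307 with an estimated correlation) and erythrocyte genes in 18 of 18 members (adjusted p = 9.62e-09, or adjusted p = 0.297 with an estimated correlation).

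Few genes separated neighbouring doses. Between 1 and 0.3 ppm limma called 0 genes, with 240 at an unadjusted p under 0.05, and so did the fit with a term for the replicate number. Between 0.3 and 0.03 ppm 1 gene was called, FO904928.1 (adjusted p = 0.00391), with 319 at an unadjusted p under 0.05. With a term for the replicate number the same gene alone was called. That call ended without 0.3 ppm replicate 1, without all libraries of replicate 1 or of replicate 3, and with only the 2 groups in the fit. A gene such as fbxo32 or krt96 that was called at 0.3 ppm and not at 0.03 ppm is therefore not shown to differ between these doses.

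Fold changes of pairs of doses were compared across the 22320 tested genes, which are not independent replicates. Pearson's r was 0.639 for 0.03 and 0.3 ppm, 0.569 for 0.03 and 1 ppm and 0.701 for 0.3 and 1 ppm, and Spearman's rho was 0.571, 0.458 and 0.630. The 3 controls enter every fold change. In 100 simulations all 12 libraries were drawn anew, controls included, without changed genes and with equal spread in every group. Doses shared their controls there, and the mean r was 0.5013, 0.5004 and 0.4996, with 0.525 the highest of all. The simulated mean of rho was 0.467, 0.466 and 0.466. For 0.03 and 1 ppm the observed rho was not above the simulated mean. Genes of the same sign made up 66.0% for this pair against 66.7% in the simulations. The covariance exceeded the simulated mean by 0.0195, 0.0182 and 0.0313. Genes called lower at both doses of a pair numbered 13, 13 and 23. The simulations held no changed genes and gave at most 0 shared calls, so they cannot show whether the shared controls produced this overlap. They also drew genes independently, so their r may vary less than it would for genes that vary together. Equal spread in every group sets their r near 0.50 by design. The real libraries differ in spread, with estimated weights from 0.355 to 5.74, and share deviations by replicate number. Either can move r, so an excess over the simulations does not show agreement of the doses beyond the shared controls.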

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

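Of the tests in this part, those on scaling, on leukocytes, on a difference of the controls other than PFOS, on the share of the main tissue, the splits within replicate numbers and all 3 on FO904928.1 were chosen only after the result was seen.

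FO904928.1 was singled out by a difference between groups: its effect against the control differed between 0.3 and 0.03 ppm in a test of the difference itself (limma adjusted p = 0.00391). It was listed at 0 in all 6 libraries of the control and 0.03 ppm and at 16 to 72 normalised counts in all 6 of 0.3 and 1 ppm. Too few reads are argued against, since at the lowest of these values at least 12.8 reads would be expected in each library listed at 0. Reads shared with a near-identical gene and a sequence variant carried by the parents of some larvae cannot be told apart from a response to PFOS, because no sequence was at hand and the labels name no parents. The number of genes with the mirror pattern was 0, and the number with the same on and off pattern was 1, FO904928.1 itself, which leaves both explanations open.

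The 13 genes called lower at all 3 doses, trim63a and calcoco1b among them, had a median absolute log2 fold change of 1.94, 2.07 and 2.07 from the lowest to the highest dose, against 1.59, 2.09 and 2.24 for all 36 genes called at any dose. Of those 36, 13 were called at 0.03 ppm and 31 at 1 ppm, a selection that favours larger changes at 1 ppm. Scaling of the libraries is argued against: the highest median log2 fold change of the 13 at 1 ppm was -2.05 over 4 scalings, while the median of all genes stayed within 0.04 of 0. An even loss of all leukocytes is argued against as the whole cause. Neutrophil and macrophage markers had a median of -0.26 at 1 ppm, with quartiles of -0.47 and -0.13. The 13 ranged from -3.08 to -0.91, but being called at every dose selects large falls. Of the 32 markers, 1 is also held by another list, 0 are among the 13 and 2 fell below -1. mpeg1.2, a macrophage gene outside this list, had -1.79, and a loss of a particular kind of leukocyte was not tested. A response that grows from 0.03 to 1 ppm stays open, because the slope over the 9 dosed libraries was -0.04 per step (exact permutation p = 0.627). A difference between the control larvae and all dosed larvae other than PFOS cannot be told apart from a PFOS effect on these 13: the lowest control lay 1.44 above the highest dosed library in mean log2 value, and the same 3 controls enter every comparison.

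The liver list was higher at 1 ppm, in part because of a low control replicate 3. The list took 0.878% of the counts there, against 1.15% and 1.26% in control replicates 1 and 2. A lower share of a main tissue that raises every other cell type alike is argued against as the whole cause. Of all 17 other tissue and cell type lists, 9 had a median log2 fold change above 0. In 13 the upper quartile lay below the lower quartile of 0.40 of the liver list. The exceptions were the erythrocyte, intestine, cartilage and heart lists. That count follows in part from choosing the list with the largest median, and such a shift with a further rise of liver genes is not excluded. A larger share of liver RNA is a candidate explanation that stays open: 93.5% of the members, 29 of 31, lay within 2 SE of the list's median, between the bounds set for and against it, and 7 of the 31 also stand in another list. tfa and apobb.1, among the most abundant members, had log2 fold changes of 1.04 and 1.04. A rise with the PFOS dose also stays open, with a slope of 0.16 per step and a permutation p of 0.0897 over the 12 libraries. That permutation ignored the replicate numbers. From the control to 1 ppm the list's mean log2 value was 11.09, 11.07, 10.89 and 11.47 in replicate 1. It was 11.23, 11.27, 10.62 and 11.38 in replicate 2, and 10.47, 11.06, 11.6 and 11.63 in replicate 3. Only in replicate 3 did it rise at every step.

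Other splits of the same libraries were refitted with limma. For each dose against the control the 10 splits are too few for a share under 0.05: at 0.03 ppm the real split, the only 1 of 10 to reach its own count, called 13 genes and the highest other 1, at 0.3 ppm 29 and 0, and at 1 ppm 31 and 0. For 0.3 against 0.03 ppm they are also too few, with 1 gene for the real split and 1 for the highest other, so that 2 of 10 reached it. The real split parts all 3 same-number pairs, as do 3 others, and at 0.3 and 1 ppm against the control and between neighbouring doses those others called 0 genes. For 1 against 0.3 ppm the real count was 0, which all 10 splits reached, and the split that put 0.3 ppm replicates 1 and 2 with 1 ppm replicate 2 called 83, which points to a structure of the samples apart from dose. For the joint test 2 of 100 splits, the real one included, gave as many as 21 genes, the highest other 25. For the trend 3 of 100 gave as many as 3, the highest other 6. Both shares are under 0.05, without adjustment over the comparisons, and some shuffled groupings called more genes than the real one. The joint test also had 522 genes at an unadjusted p under 0.05, where chance alone gives 1116. With groups shuffled only among libraries of the same replicate number, 3 of 100 splits reached 21 (highest other 22) and 1 of 100 reached 3 (highest other 2), although the trend called 0 genes without any 1 of the 3 controls.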

How the results depend on the processing

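The settings with pseudocounts 0.5 and 8, quantile normalization, library weights, robust empirical Bayes, list tests without single controls and an estimated correlation with the replicate term were chosen only after the data were seen. DESeq2, limma-voom, the likelihood ratio dose pattern and the edgeR fits were not run, because the values are not raw counts. Against the counts of 13, 29, 31, 21 (joint) and 3 (trend), equal totals, in place of the planned total count scaling, gave 6, 18 and 21 at the doses and 8 jointly. A replicate term gave 20, 43, 58, 39 and 9, and 36 genes lower at every dose against 20. Fitting only 2 groups, with fewer libraries to estimate the spread, gave 3, 10 and 3, and 0 for 0.3 against 0.03 ppm. The trend called 0 with the dose in ppm or pseudocount 8 and 5 with quantile normalization, and pseudocount 8 gave 0 for 0.3 against 0.03 ppm. Library weights gave 57, 95, 768, 188 and 882, with 335 higher and 433 lower at 1 ppm; control replicate 3 then weighed 5.74 and control replicate 1 0.355. Where no cause is named, the cause was not tested. Leaving out libraries gave 0 to 11 genes at 0.03 ppm, 0 to 18 at 0.3, 0 to 47 at 1, 0 to 23 jointly, 0 to 30 for the trend, 0 for 1 against 0.3 ppm and 0 to 1 for 0.3 against 0.03 ppm. Without replicate 1 the 3 doses called 0, 0 and 0, without replicate 3 also 0, and without replicate 2 7, 18 and 26; an arm then holds 2 libraries and shares the spread of the others. Recomputed size factors, no filter, a filter at 1 CPM, pseudocount 0.5 and robust empirical Bayes kept each count within 1.5 times. Lists called were 10 to 16, 9 to 20 (19 and 14 without replicates 1 and 3, 12 without control replicate 3), 18 to 24 and 17 to 25 (trend) in these leave-outs, and 0 with an estimated correlation, with fry's test for 1 direction or with an estimated correlation and the replicate term. With that term alone the respiratory chain list at 0.03 ppm ended at adjusted p = 0.0709. Reversed lists had adjusted p of 0.934 and 0.210 (neurons, 0.03 ppm, without replicate 1 and control replicate 1), 0.979 and 0.704 (liver, 0.03 ppm, replicate 3 and control replicate 3), 0.599 (respiratory chain, 0.03 ppm, replicate 3), and 0.720 and 0.960 (leukocytes, 0.3 ppm, replicate 2 and control replicate 2). Of the other values of called lists, 415 were still called in the same direction and 202 kept their direction but were no longer called. For called genes these were 1028 and 600, with 0 reversed. Among genes with at least 10 CPM the r between doses was 0.654, 0.544 and 0.739. Small changes are poorly resolved at this depth and spread, which were not varied: 4% of simulated 1.5-fold changes were recovered at 1 ppm.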

Other observations

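No test in this part was chosen after its result was seen, whereas the omission of control replicate 3 from the exocrine shares was. The stress and hypoxia gene igfbp1b, a binding protein of insulin-like growth factor, had 289 ± 64.4 normalised counts in the control, 94.7 ± 63.9 at 0.03 ppm, 90.3 ± 21.7 at 0.3 ppm and 118 ± 41.0 at 1 ppm, and was called at 0.03 and 0.3 ppm when adjusted over the list alone but not over all genes (limma adjusted p = 0.367 and 0.373). The fatty acid elongase gene elovl2 had 785 ± 164 in the control and 1667 ± 529 at 1 ppm, and the desaturase gene fads2 had 623 ± 255 and 1107 ± 20.5, neither of them called. cyp1a, the target of the aryl hydrocarbon receptor, had 364 ± 56.6 and 547 ± 120, and apoa1a 30988 ± 3627 and 60174 ± 19994, again without a call. Exocrine pancreas genes were lower in 21 of 21 members at 0.3 ppm and in 18 of 21 at 1 ppm, with camera adjusted p of 0.141 and 0.0866. Control replicate 3 stood apart in this list, which took 0.152%, 0.2198% and 0.530% of the counts in control replicates 1, 2 and 3, against 0.193%, 0.238% and 0.2497% at 0.3 ppm and 0.123%, 0.221% and 0.276% at 1 ppm. Without that library the mean share at neither dose was below that of the controls.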
